A study of Caenorhabditis elegans with 12 samples.

How the data were processed

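RNA was taken from whole L4 animals and read as polyA-selected, randomly primed libraries, per the labels' protocols. No molecular identifiers were used and the strandedness is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Each of the 12 samples has 1 deposited table with a row for each of 36172 transcripts. Per the file headers, each table gives the effective length, the estimated count and the TPM (transcript share scaled to a common total and corrected for length) of every transcript. The authors made these estimated counts and TPM values by kallisto 0.45.0 pseudoalignment to WBcel235 transcripts, and FastQC 0.11.5 and sleuth 0.30.0 were also listed, per the submitters' processing notes. Kallisto shares reads that fit several transcripts among them, so near-identical genes, such as some vitellogenins, major sperm proteins, histones, small heat shock genes, rpl-41.1 and rpl-41.2, are uncertain one by one. TPM values are relative to each library's total, so a change in a few abundant genes moves all others.

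Estimated counts were summed over the transcripts of each gene and rounded to whole numbers. Transcripts were matched to the Ensembl annotation of WBcel235, 31502 by transcript identifier and 4581 by sequence name. The other 89 transcripts, which held at most 0.0226% of the TPM of any library, kept their own names. This gave 22113 genes. Library totals were 21581129 to 40046724 estimated counts and were mostly higher in the mutant libraries. Coordinates are 1-based WBcel235 positions of whole genes. No genome sequence was used here, so GC content was not checked.

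Groups were taken from the sample labels, as 2 genotypes on 2 bacteria with 3 replicates each. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries agreed within sampling noise, and all were kept. Chi-square per degree of freedom between replicates was 2.65 to 4.22 in wild type and 8 to 12 in rotr-1, whose libraries were mostly deeper. The main fit shares 1 estimate of the spread per gene between the genotypes. Genes with too few counts were removed with edgeR's filterByExpr, which left 16924. Normalization was by TMM. The main test was edgeR 4.0.16's robust quasi-likelihood test (glmQLFit and glmQLFTest, in R 4.3.3) in 1 fit of all 12 libraries with the 4 group means, with 8 residual degrees of freedom, a common biological coefficient of variation of 0.0576 and Benjamini-Hochberg adjustment within each of the 5 comparisons. Genes with an adjusted p under 0.05 were counted as changed. All adjusted p-values given for genes come from this test unless another tool is named. Fold changes carry a standard error (SE) derived from the test, as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. CPM values (counts over the TMM-scaled library total, times 1e+06) are means of 3 libraries. The interaction is the PA14 change in rotr-1 minus that in wild type.

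A total of 31 gene lists was fixed before the data were examined, from general knowledge of the worm. They cover p38 effectors, the p38 cascade, ZIP-2 infection response genes, C-type lectins, lysozymes, antimicrobial peptides, the intracellular pathogen response, vacuolar ATPase, lysosome, lysosome-related organelles, autophagy, DAF-16 targets, SKN-1 detoxification, cytochrome P450, UDP-glucuronosyltransferases, glutathione S-transferases, heat shock, both unfolded protein responses, metal response, lipid metabolism and ribosomal proteins. Markers of stage and of other tissues cover vitellogenins, collagens, molting, sperm, germline and oocytes, neurons, muscle, hypodermis and intestine. Lists were tested with camera (limma 3.58.1, two-sided) at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the 31 lists within a comparison. Members tmem-175, rab-32, atg-11, dod-8 and daf-21 were not matched. Whether the p38 and pathogen response lists were first drawn up on similar libraries is not given in the sources used here.

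The named genes were fixed by a rule before the data were examined. It takes T24B8.5, irg-1, irg-2, irg-4, irg-5, irg-6, tir-1, nsy-1, sek-1, pmk-1, atf-7, vhp-1, hlh-30 and rotr-1 in every comparison. It adds the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM and, between 2 groups, no overlap between libraries. It also adds up to 4 members of each list with a camera call, in the list's direction, and any member where at most 5 of a list pass. For the agreement of comparisons, correlations and shared calls across genes were set beside lists drawn independently, and, where the control libraries were shared, beside 20 simulations of unchanged groups.

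The test scripts were tested on simulated data, with counts drawn for 16924 genes from the real means and library sizes and 200 changed genes. At 1.5-fold, 2-fold and 4-fold, edgeR recovered 70.1, 80.6 and 95.5% of changed genes for PA14 in wild type and 62.7, 88.1 and 93.9% for rotr-1 on OP50. It recovered 59.7, 82.1 and 92.4% for rotr-1 on PA14, 58.2, 88.1 and 100% for PA14 in rotr-1, and 46.3, 73.1 and 93.9% for the interaction. Between 6.29 and 8.24% of the calls were of unchanged genes. The real comparisons called 2186 to 12266 genes, far more than the 200 changed here, which moves the threshold of the adjustment. These shares of recovered and false calls therefore need not hold for them. A difference of 1.5-fold that did not pass is still not shown to be absent.

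Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, no filter, a filter of 5 CPM in 3 samples, length-scaled TPM counts, limma on log2(TPM + 1) with and without a minimum mean TPM of 1, limma on log2(TPM + 0.1), the libraries of the compared groups alone, the replicate number as a block, an adjusted p under 0.01, a 2-fold minimum, each library left out in turn and camera with an estimated correlation. Thinning to equal depth, transcript length offsets and the mean of the molting list as a covariate were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.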

Results

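Messenger RNA was sequenced from whole Caenorhabditis elegans, a bacteria-feeding nematode, at the L4 larval stage. Wild-type animals carried a GFP reporter driven by the promoter of T24B8.5, an intestinal immune effector gene that depends on the p38 MAP kinase PMK-1. The annotation names this gene sysm-1 (WBcel235 chromosome II, 9082626 to 9083193). The mutants carried the ums53 allele of rotr-1 in the same reporter background. Both genotypes spent 4 h at 25 °C either on Escherichia coli OP50, the standard laboratory food, or on Pseudomonas aeruginosa PA14, a pathogen that infects the worm intestine. Each of the 4 groups held 3 libraries. Total estimated counts were 21581129 to 33003768 in the 6 wild-type libraries and 31877625 to 40046724 in the 6 mutant libraries, and 16924 of 22113 genes had enough counts to be tested. Principal component 1, with 65.2% of the variance, separated the genotypes, and principal component 2, with 16.9%, separated the bacteria.

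The mutated gene itself was nearly silent in every mutant library. The rotr-1 gene (chromosome III, 6149961 to 6154940) had 124, 100 and 117 counts in wild type on OP50 and 178, 155 and 200 on PA14. The mutant libraries held 3, 2 and 2 counts on OP50 and 1, 0 and 5 on PA14. Summed over 3 libraries and scaled for depth, the mutant level was 1.2% of wild type on OP50 (exact binomial 95% interval 0.478 to 2.49) and 0.894% on PA14 (0.327 to 1.96), where the intervals cover counting error only. Every library matched its genotype label by this measure. The transcript did not pass the test for a change on PA14 in wild type (log2 0.33 ± 0.164 SE, edgeR, adjusted p = 0.128).

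The series describes PA14 against OP50 in wild type as its measure of the response to infection. Exposure for 4 h raised immune effector genes by as much as 178-fold. The transcript of irg-6, a p38-dependent infection response gene, rose from 0.276 to 49 CPM (log2 7.48 ± 0.205 SE, n = 3 per group, edgeR, adjusted p = 9.25e-18). This largest fold starts near the floor, from 6, 4 and 8 counts in the wild-type libraries on OP50. The related genes irg-5 and irg-4 rose by log2 5.52 ± 0.28 and 4.52 ± 0.258, to 177 and 110 CPM. The T24B8.5 transcript itself, sysm-1, rose from 7.02 to 16.3 CPM (log2 1.23 ± 0.139). In the other direction acdh-1, an acyl-CoA dehydrogenase of the propionate breakdown shunt whose level depends on the vitamin B12 supply of the bacterial diet, fell from 1592 to 113 CPM (log2 -3.81 ± 0.119).

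Among 25 tested p38-dependent effectors 23 rose and 1 fell (24 and 1 adjusted over the list alone), with a median log2 change of 2.25. The list stood above other genes in camera (adjusted p = 2e-111, adjusted p = 0.000768 with an estimated correlation). C32H11.4 reached 431 CPM from 9.58 and F55G11.2 reached 326 CPM from 8.77. The infection response genes of the ZIP-2 arm, a bZIP pathway that acts in parallel to p38, showed 9 rises and 2 falls among 12 (10 and 2 adjusted over the list alone). Their median was 1.11 (camera, adjusted p = 7.54e-18, adjusted p = 0.000768 with an estimated correlation). In the ZIP-2 arm irg-3 rose by log2 4.94 ± 0.094, irg-1 by 4.12 ± 0.153 and irg-2 by 2.71 ± 0.153. These were the 2 lists of 14 whose camera call held with an estimated correlation in this comparison.

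The p38 cascade and its regulators moved much less than the effectors, with 9 rises and no fall among 17 genes, also adjusted over the list alone. The list median was 0.13 (camera, adjusted p = 0.00503, adjusted p = 0.288 with an estimated correlation). The transcript of tir-1, the SARM1 orthologue at the top of the cascade, rose from 31.4 to 66.5 CPM (log2 1.08 ± 0.063). The MAP kinase phosphatase vhp-1, which restrains the cascade, rose by log2 1.06 ± 0.079. The MAP3 kinase nsy-1 changed by 0.34 ± 0.059, a call lost once transcript length was corrected, and hlh-30, the TFEB orthologue that drives lysosomal and immune genes, by 0.42 ± 0.059. The kinases sek-1 and pmk-1 did not pass (log2 0.07 ± 0.05 and 0.02 ± 0.065, edgeR, adjusted p = 0.273 and 0.834), although both passed in a limma test on TPM. The downstream transcription factor atf-7 was at log2 0.13 ± 0.047 (edgeR, adjusted p = 0.0315), a call lost in 5 of the 6 fits without 1 library.

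Detoxification genes rose beside the immune effectors. Of 21 SKN-1-linked stress and detoxification genes 16 rose and 4 fell, also adjusted over the list alone (median 0.84, camera, adjusted p = 4.03e-12, adjusted p = 0.0591 with an estimated correlation). The glutathione S-transferase gst-38 rose from 4.66 to 146 CPM and gst-5 from 25.7 to 96.5 CPM. Over all 42 glutathione S-transferase genes 18 rose and 5 fell (19 and 6 adjusted over the list alone, camera, adjusted p = 2.4e-05, adjusted p = 0.194 with an estimated correlation). Cytochrome P450 genes showed 26 rises and 12 falls among 66 (27 and 12 adjusted over the list alone, camera, adjusted p = 0.0284, adjusted p = 0.547 with an estimated correlation), including cyp-13B1 at log2 3.04 ± 0.224 and cyp-35C1 at 2.73 ± 0.262. In the C-type lectin family 43 rose and 28 fell among 166 (45 and 30 adjusted over the list alone, camera, adjusted p = 0.000909, adjusted p = 0.206 with an estimated correlation), with clec-174 at log2 6.55 ± 0.242 and clec-67 at 3.5 ± 0.071. The glutathione S-transferase, P450 and lectin calls were lost in at least 1 limma test on TPM.

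Further immune and stress lists were called as well. Of 45 intracellular pathogen response genes 10 rose and 2 fell (9 and 2 adjusted over the list alone, median 0.37, camera, adjusted p = 0.039, adjusted p = 0.288 with an estimated correlation), a call lost under limma on TPM and without wild-type replicate 2 or 3 on OP50. Autophagy genes showed 16 rises and 4 falls among 33, also adjusted over the list alone (median 0.16, camera, adjusted p = 0.0216, adjusted p = 0.26 with an estimated correlation), with the cargo receptor sqst-1 at log2 1.32 ± 0.057. Of 22 genes of the endoplasmic reticulum unfolded protein response 12 rose and none fell (13 and 1 adjusted over the list alone, camera, adjusted p = 0.00503, adjusted p = 0.548 with an estimated correlation), including the chaperone hsp-4 at log2 0.73 ± 0.051. Of 13 genes of the mitochondrial counterpart 7 fell and 1 rose, also adjusted over the list alone (median -0.26, camera, adjusted p = 0.0254, adjusted p = 0.194 with an estimated correlation), with hsp-60 at log2 -0.67 ± 0.062. The last call was lost under limma on TPM.

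Yolk and ribosomal protein genes fell. All 6 vitellogenins, the yolk proteins made by the adult intestine, fell (also adjusted over the list alone), with a median of -1.63 and with vit-1 at log2 -2.51 ± 0.171 (camera, adjusted p = 2.4e-05, adjusted p = 0.288 with an estimated correlation). Some vitellogenin genes are near-identical in sequence, so the split of reads between those is uncertain. Of 84 ribosomal protein genes 76 fell and none rose (79 and 0 adjusted over the list alone), by a median of only -0.26 (camera, adjusted p = 3.6e-10, adjusted p = 0.418 with an estimated correlation). Lipid metabolism genes went both ways, with 15 rises and 17 falls among 41 (15 and 19 adjusted over the list alone). Camera called the list towards lower (adjusted p = 0.00608, adjusted p = 0.194 with an estimated correlation). Its largest falls included acdh-1, hacd-1 (log2 -3.1 ± 0.077) and the fatty acid elongase elo-6 (-2.19 ± 0.06), and its median of -0.08 turned positive under limma on TPM.

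Most lists with no camera call in this comparison had members that moved in both directions. Of 22 vacuolar ATPase subunits, which acidify the lysosome, 2 rose and 7 fell, and of 55 lysosomal hydrolases and membrane proteins 20 rose and 16 fell (20 and 17 adjusted over the list alone). Of 39 genes of lysosome-related organelles 6 rose and 13 fell. Lysozymes had 5 rises and 6 falls among 12, antimicrobial peptides 14 and 11 among 42 (14 and 13 adjusted over the list alone), DAF-16 targets 8 and 6 among 18, UDP-glucuronosyltransferases 22 and 24 among 65 (24 and 24 adjusted over the list alone), and metal-responsive genes 10 and 7 among 23. Markers of intestine had 12 rises and 9 falls among 28 (13 and 9 adjusted over the list alone), and markers of muscle 5 and 10 among 28 (6 and 10 adjusted over the list alone). Germline and oocyte genes had 11 falls and no rise among 37, just outside the camera threshold (adjusted p = 0.0529). Collagens had 13 rises and 38 falls among 149, sperm genes 5 and 8 among 57 (4 and 7 adjusted over the list alone), molting genes 5 and 1 among 32 (3 and 1 adjusted over the list alone), heat shock genes 6 and 4 among 15, neuronal markers 9 and 2 among 34 and hypodermal markers 1 and 3 among 19. Counts for the lists given without such a pair were equal when adjusted over the list alone.

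In all, 2735 genes were higher and 3453 lower on PA14 among 16924 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 576 and 275 changed at least 2-fold. In limma on log2(TPM + 1) 79.2% of called genes were higher, against 44.2% in the edgeR test, so the balance between rises and falls depended on the scaling.

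**Figure D1:**
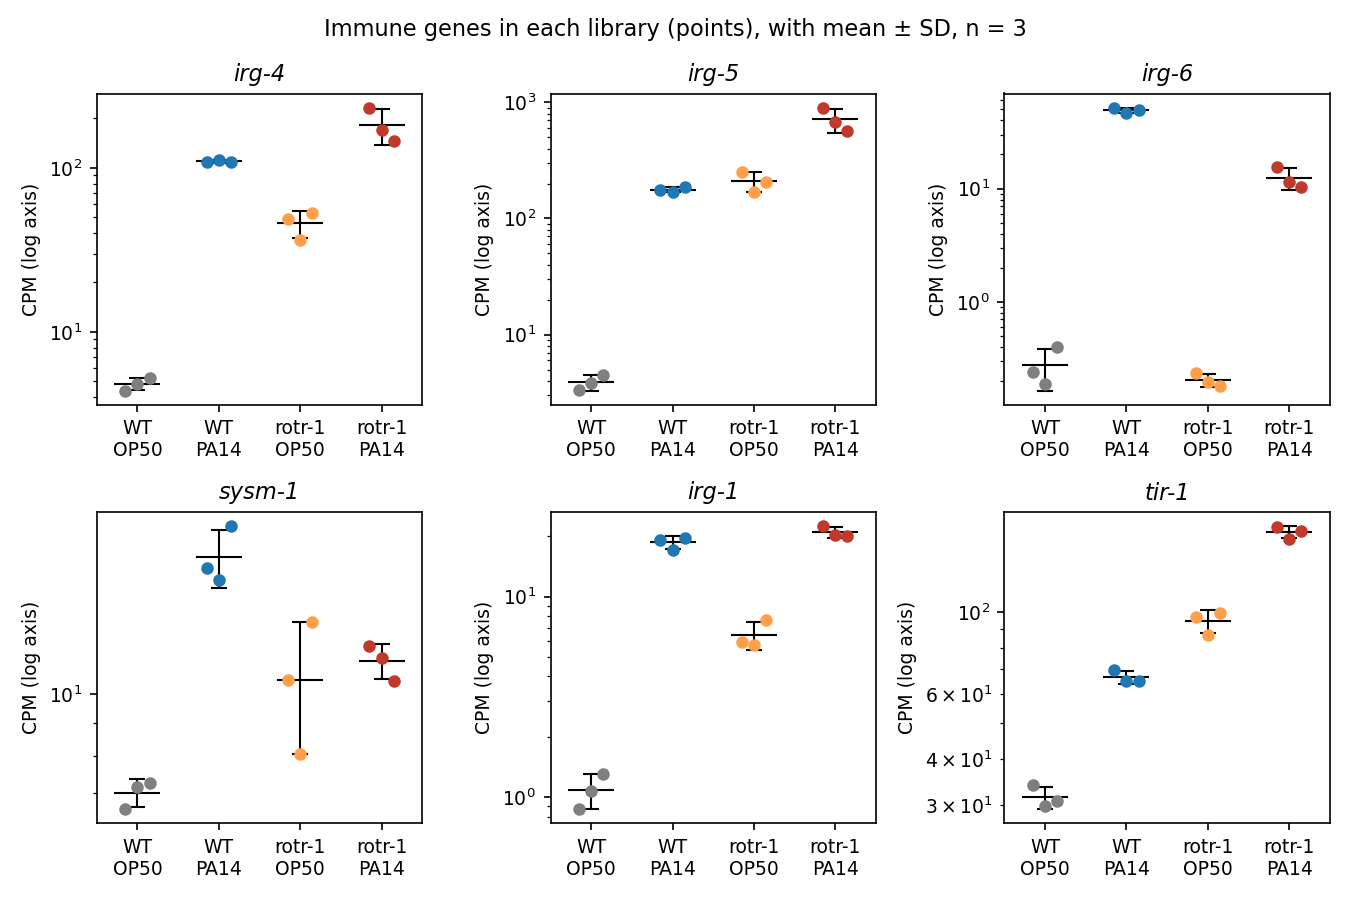
CPM values (log axis) of 6 immune genes in each of the 12 libraries, with points for libraries and black bars for the mean ± SD of each group of 3. On OP50 the rotr-1 libraries lay above wild type for irg-4, irg-5, irg-1 and tir-1 and not for irg-6, and sysm-1 went from 7.02 to 16.3 CPM on PA14 in wild type and from 10.5 to 11 CPM in rotr-1.

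The series also describes rotr-1 mutants against wild type on OP50, in the absence of the pathogen. Mutants fed OP50 already expressed several PA14-induced effectors far above the wild-type level. The irg-5 transcript was at 208 CPM, against 3.88 CPM in wild type on OP50 and 177 CPM in wild type on PA14 (rotr-1 against wild type on OP50 log2 5.76 ± 0.279 SE, n = 3 per group, edgeR, adjusted p = 8.62e-08). The mucin-like gene mul-1 rose by log2 5.45 ± 0.132 and irg-4 by 3.27 ± 0.265. The lectin clec-60, which did not pass for PA14 in wild type (log2 0.80 ± 0.31, edgeR, adjusted p = 0.0537), rose by 6.26 ± 0.168. With the molting index as a covariate, an alternative added after the data were seen, the calls of irg-5 and irg-4 were lost (log2 3.90 and 1.63, edgeR, adjusted p = 0.0806 and 0.614), and those of mul-1 and clec-60 held (4.53 and 6.13). With this covariate 21 of the 81 called genes that the fixed rule names kept their calls, and 20 named genes changed sign, none of them past the threshold. The index differs mainly between the genotypes, and under it the median standard error over all genes rose from 0.0992 to 0.452. The transcript of irg-6 stayed at 0.203 CPM, against 0.276 in wild type (log2 -0.42 ± 0.544, edgeR, adjusted p = 0.499), on 4 to 8 counts per library. In the same libraries yolk protein genes fell severalfold and molting genes rose severalfold, as given with the stage and tissue markers.

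Of the 25 p38-dependent effectors 19 were higher and 3 lower in rotr-1, also adjusted over the list alone, with a median of 1.23 (camera, adjusted p = 9.45e-18, adjusted p = 0.118 with an estimated correlation). The sysm-1 transcript was higher by log2 0.58 ± 0.141. Of the 17 cascade genes 9 were higher and 3 lower, also adjusted over the list alone (camera, adjusted p = 0.00874, adjusted p = 0.351 with an estimated correlation). In this group tir-1 rose 3-fold to 94.5 CPM (log2 1.59 ± 0.062), vhp-1 by log2 1.37 ± 0.078, nsy-1 by 0.68 ± 0.058 and hlh-30 by 0.67 ± 0.059. The pmk-1 transcript was at log2 0.05 ± 0.064 and did not pass, except in limma on TPM. Small calls for sek-1 (0.14 ± 0.049) and atf-7 (-0.15 ± 0.047) did not hold in every setting. Of 12 ZIP-2 arm genes 8 were higher and 4 lower, also adjusted over the list alone (median 0.91, camera, adjusted p = 2.3e-05, adjusted p = 0.0418 with an estimated correlation), a list call lost under limma on TPM. They included the bZIP factor cebp-1 at log2 2.74 ± 0.073 and irg-7, an intestinal gene that activates p38 immunity, at 1.70 ± 0.081. Over the same libraries the molting list had a mean of 6.18 ± 0.13 (SD) log2 CPM, against 4.71 ± 0.066 in wild type.

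Intracellular pathogen response genes, which worms induce on infection by microsporidia and Orsay virus, were the rising list with the largest median. Of 45 tested members 39 were higher and 1 lower, also adjusted over the list alone, with a median of 2.04 (camera, adjusted p = 7.29e-13, adjusted p = 0.00826 with an estimated correlation). The transcript of pals-14 rose from 1.22 to 49.1 CPM, eol-1 from 0.976 to 31.4 CPM and pals-6 from 2.05 to 32.8 CPM. This list and the ZIP-2 arm were the 2 of 16 camera calls that held with an estimated correlation. Molting genes were higher in these libraries by a similar median, 1.74.

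Genes of the lysosome and its acidification did not move as 1 group. Of 22 vacuolar ATPase subunits 19 were lower and 2 higher, also adjusted over the list alone, with a median of -0.49 (camera, adjusted p = 3.08e-06, adjusted p = 0.118 with an estimated correlation). The intestinal subunit vha-6 fell from 368 to 205 CPM (log2 -0.85 ± 0.048) and vha-10 by 0.62 ± 0.046 on the log2 scale. Of 39 genes of lysosome-related organelles, the gut granules of the worm intestine, 27 were lower and 4 higher, also adjusted over the list alone (median -0.31, camera, adjusted p = 0.00281, adjusted p = 0.258 with an estimated correlation), including blos-4 at log2 -0.95 ± 0.085. With the molting index as a covariate the organelle list had a median of 0.09 and no call (camera, adjusted p = 0.565), and blos-4 turned to 0.15 (edgeR, adjusted p = 0.961). Of 55 lysosomal hydrolases and membrane proteins 20 were higher and 21 lower, also adjusted over the list alone, with no camera call (adjusted p = 0.771). Of 33 autophagy genes 15 were higher and 8 lower, also adjusted over the list alone, with no camera call (adjusted p = 0.154). Vitellogenin, germline and ribosomal lists were lower in the same libraries.

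Most lists of stage and tissue markers differed between the genotypes. Markers of muscle (14 higher and 9 lower of 28) and of intestine (13 and 10 of 28) had no camera call (adjusted p = 0.541 and 0.413). Of 32 molting genes, which peak before each larval molt, 30 were higher and 2 lower, also adjusted over the list alone (median 1.74, camera, adjusted p = 1.62e-12, adjusted p = 0.229 with an estimated correlation). The protease inhibitor mlt-11 rose by log2 2.58 ± 0.239 and the fibrillin-like fbn-1 by 2.37 ± 0.189. Of 149 collagens, the main cuticle proteins, 94 were higher and 32 lower, also adjusted over the list alone (median 0.95, camera, adjusted p = 6.92e-11, adjusted p = 0.125 with an estimated correlation), with col-46 at 2.49 ± 0.147. Of 19 hypodermal markers 16 were higher and 1 lower, also adjusted over the list alone (camera, adjusted p = 2.56e-07, adjusted p = 0.229 with an estimated correlation), with the cuticle collagen dpy-7 at 2.05 ± 0.173. Of 34 neuronal markers 27 were higher and 1 lower, also adjusted over the list alone (median 0.53, camera, adjusted p = 0.000105, adjusted p = 0.229 with an estimated correlation), with the neuropeptide convertase egl-3 at 1.03 ± 0.066. The endoplasmic reticulum list had 11 higher and 6 lower of 22, also adjusted over the list alone (camera, adjusted p = 0.0366, adjusted p = 0.605 with an estimated correlation). Its leading members abu-8 (1.40 ± 0.067) and abu-1 (1.31 ± 0.069) belong to a glutamine- and asparagine-rich family linked to the pharyngeal cuticle, and the call was lost with DESeq2 size factors. Under the covariate, which is the mean of the molting list, mlt-11 and dpy-7 turned to -0.082 and -0.17 and did not pass.

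Most genes of the yolk, germline and sperm lists were lower. All 6 vitellogenins fell, also adjusted over the list alone, by a median log2 of -3.16, and vit-3 went from 1863 to 116 CPM (camera, adjusted p = 6.5e-08, adjusted p = 0.21 with an estimated correlation). Of 37 germline and oocyte genes 36 were lower and none higher, also adjusted over the list alone (median -0.70, camera, adjusted p = 2.17e-10, adjusted p = 0.351 with an estimated correlation), with the oocyte maturation gene oma-2 at log2 -1.16 ± 0.079. Under the molting covariate oma-2 stood at 0.085 (edgeR, adjusted p = 0.964), and the germline list had a median of 0.23 and no call (camera, adjusted p = 0.0652). Of 57 sperm genes 40 were lower and 6 higher (41 and 6 adjusted over the list alone, median -0.29, camera, adjusted p = 0.013, adjusted p = 0.612 with an estimated correlation). The list holds many near-identical major sperm protein copies, in which reads may be split. Not all sperm genes fell. The genes spe-9, spe-11 and spe-41, picked after the values were seen, were higher in every rotr-1 library than in any wild-type one. They stood at 10.9 to 11.9, 39.2 to 40.8 and 48.4 to 54.3 CPM in rotr-1. Wild-type libraries held 5.51 to 6.75, 28.2 to 32 and 29.5 to 36.4 CPM. Of 84 ribosomal protein genes 78 were lower and 1 higher, also adjusted over the list alone (median -0.35, camera, adjusted p = 7.74e-09, adjusted p = 0.437 with an estimated correlation). Of 21 SKN-1-linked genes 11 were lower and 4 higher, also adjusted over the list alone (camera, adjusted p = 0.0247, adjusted p = 0.437 with an estimated correlation), including the oxidative stress reporter gene gst-4 at log2 -1.64 ± 0.075. Among the largest single falls were ilys-5, an invertebrate-type lysozyme, from 323 to 14.3 CPM and the arginine kinase argk-1 from 25.5 to 1.90 CPM.

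Most tested genes differed between the genotypes on OP50, with 6405 higher and 5861 lower in rotr-1, or 72.5% of 16924 (edgeR), of which 2257 and 689 changed at least 2-fold. With the molting index as a covariate 253 genes were called and the median standard error rose from 0.0992 to 0.452. In limma on log2(TPM + 1) 70.6% of called genes were higher, against 52.2% in edgeR.

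**Figure D2:**
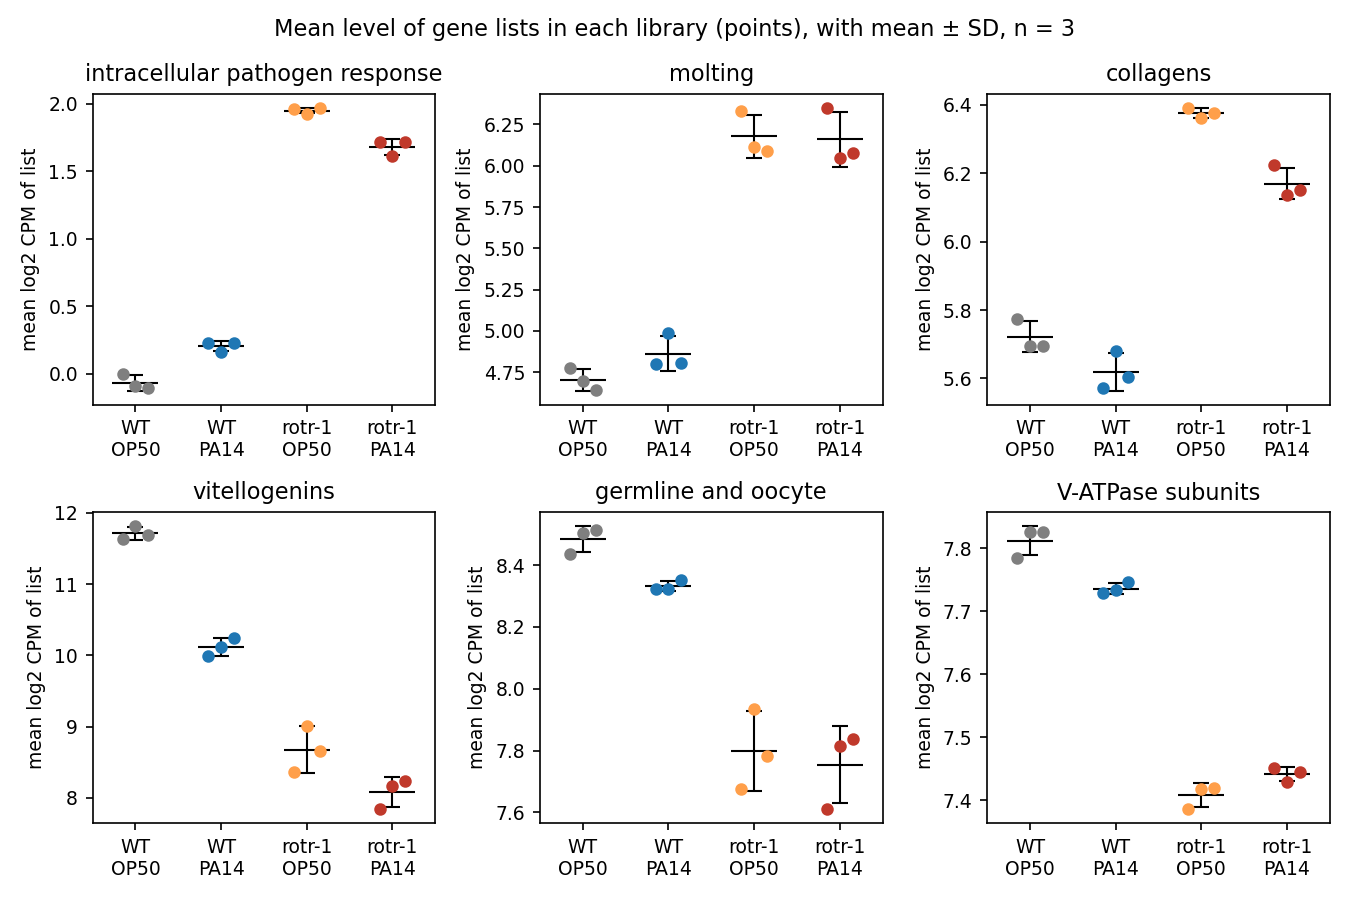
Mean log2 CPM of 6 gene lists in each library, with points for libraries and black bars for the mean ± SD of each group of 3, on vertical axes that differ between panels and do not start at 0. Intracellular pathogen response, molting and collagen lists were higher and vitellogenin, germline and vacuolar ATPase lists lower in rotr-1 on both bacteria.

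On PA14 the genotypes differed in a more mixed way. The irg-6 transcript reached 49 CPM in wild type and 12.5 CPM in rotr-1 (log2 -1.97 ± 0.106 SE, n = 3 per group, edgeR, adjusted p = 2.13e-12), while irg-5 reached 177 CPM in wild type and 715 CPM in rotr-1 (log2 2.02 ± 0.191). Among the 25 p38-dependent effectors 9 were higher and 15 lower in rotr-1, also adjusted over the list alone. The list median was -0.35, its mean 0.07, and camera made no call (adjusted p = 0.401). With the molting covariate, however, the median was -0.75 and the list was called towards lower (camera, adjusted p = 1.29e-05). The index itself differed between the genotypes by 1.3 log2 CPM on PA14, so this fit cannot part stage from genotype. Under it the median standard error over all genes rose from 0.0968 to 0.403. The sysm-1 transcript was lower (log2 -0.54 ± 0.124) and irg-4 higher (0.74 ± 0.179), whereas irg-1 and irg-2 did not pass (0.17 ± 0.094 and 0.14 ± 0.107, edgeR, adjusted p = 0.118 and 0.27), irg-1 except in 2 alternative settings. With the molting index as a covariate irg-4 turned to -0.73 and irg-5 stood at 0.36 (edgeR, adjusted p = 0.922 and 0.976), sysm-1 at -0.40 did not pass (edgeR, adjusted p = 0.968), and irg-6 stayed lower (log2 -3.13, edgeR, adjusted p = 0.000759). The largest falls among well-expressed genes included cld-1 and dod-21, neighbours on chromosome IV (12935011 to 12936271 and 12936738 to 12937988), at log2 -3.98 ± 0.206 and -3.69 ± 0.237.

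Most other lists that differed on OP50 were called in the same direction on PA14. The ZIP-2 arm lost its call, with 5 higher and 4 lower of 12 (median 0.15, camera, adjusted p = 0.069). So did the endoplasmic reticulum list, with 9 higher and 8 lower of 22 (camera, adjusted p = 0.553). Of 45 intracellular pathogen response genes 31 were higher and 1 lower (32 and 1 adjusted over the list alone, median 1.51, camera, adjusted p = 1.21e-10, adjusted p = 0.0375 with an estimated correlation), the single camera call of 14 that held with an estimated correlation. The 17 cascade genes had 11 higher and 1 lower, also adjusted over the list alone (camera, adjusted p = 0.0138, adjusted p = 0.366 with an estimated correlation), with tir-1 at 165 CPM against 66.5 in wild type (log2 1.31 ± 0.058). Of 22 vacuolar ATPase subunits 19 were lower and 3 higher, also adjusted over the list alone (camera, adjusted p = 2.13e-05, adjusted p = 0.232 with an estimated correlation), with vha-6 at log2 -1.17 ± 0.048. The organelle list had 23 lower and 5 higher of 39, also adjusted over the list alone (camera, adjusted p = 0.00301, adjusted p = 0.305 with an estimated correlation). Heat shock genes had 8 higher and 1 lower of 15, also adjusted over the list alone (median 0.57, camera, adjusted p = 0.0111, adjusted p = 0.336 with an estimated correlation), including the small heat shock gene hsp-16.2 at 1.06 ± 0.069. On OP50 they had 9 higher and 4 lower with a median of 0.72 but no camera call (adjusted p = 0.136). The interaction was not called for this list (camera, adjusted p = 0.422), so the difference is not shown to be particular to PA14. The heat shock list holds T27E4.3 and T27E4.9, both named hsp-16.48, whose counts were equal in every library. Counts, medians and p-values of the list treat them as separate genes in every comparison, although they are not independent. The SKN-1-linked list had 11 lower and 5 higher of 21, also adjusted over the list alone (camera, adjusted p = 0.0436, adjusted p = 0.575 with an estimated correlation), a call lost without rotr-1 replicate 2 or 3 on PA14.

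Most lists of stage and tissue markers differed on PA14 too. Of 32 molting genes 30 were higher and 2 lower (median 1.44, camera, adjusted p = 1.23e-14, adjusted p = 0.232 with an estimated correlation), of 149 collagens 95 were higher and 31 lower (camera, adjusted p = 4.29e-11, adjusted p = 0.232 with an estimated correlation), and of 19 hypodermal markers 17 were higher and 1 lower (camera, adjusted p = 8.97e-09, adjusted p = 0.232 with an estimated correlation). Neuronal markers had 28 higher and 1 lower of 34 (camera, adjusted p = 5.51e-06, adjusted p = 0.232 with an estimated correlation). All 6 vitellogenins were lower, by a median of -1.76 (camera, adjusted p = 1.82e-06, adjusted p = 0.268 with an estimated correlation), as were 35 of 37 germline genes (camera, adjusted p = 4.29e-11, adjusted p = 0.366 with an estimated correlation). Counts for these 6 lists were equal when adjusted over the list alone. Of 57 sperm genes 41 were lower and 3 higher (42 and 3 adjusted over the list alone, camera, adjusted p = 1.25e-06, adjusted p = 0.408 with an estimated correlation). Markers of muscle and intestine again had no camera call (adjusted p = 0.872 and 0.4). Of 84 ribosomal protein genes 53 were lower and 2 higher, also adjusted over the list alone (camera, adjusted p = 0.00324, adjusted p = 0.748 with an estimated correlation), a call lost under limma on TPM. In total 5739 genes were higher and 5300 lower in rotr-1 on PA14 (edgeR), of which 1523 and 503 changed at least 2-fold, and 178 were called with the molting index as a covariate. In limma on log2(TPM + 1) 65.2% of called genes were higher, against 52% in edgeR.

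In rotr-1 mutants PA14 still raised immune and detoxification genes. The irg-6 transcript rose from 0.203 to 12.5 CPM (log2 5.92 ± 0.218 SE, n = 3 per group, edgeR, adjusted p = 4.72e-15) and C32H11.4 from 4.56 to 151 CPM (log2 5.04 ± 0.093). The changes of irg-5, irg-4 and irg-1 were log2 1.78 ± 0.189, 1.99 ± 0.187 and 1.70 ± 0.101. The sysm-1 transcript did not pass, at 10.5 CPM on OP50 and 11 CPM on PA14 (log2 0.10 ± 0.125, edgeR, adjusted p = 0.653). The falls of acdh-1 (log2 -3.66 ± 0.118), of the peroxisomal transporter gene pmp-5 (-3.51 ± 0.065) and of the aspartyl protease gene asp-13 (-3.37 ± 0.086) stood beside -3.81, -3.80 and -3.54 in wild type.

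Of the 25 p38-dependent effectors 20 rose and 2 fell, also adjusted over the list alone, with a median of 0.57 (camera, adjusted p = 1.08e-36, adjusted p = 0.0155 with an estimated correlation). Of 12 ZIP-2 arm genes 8 rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 1.38e-13, adjusted p = 0.00334 with an estimated correlation). SKN-1-linked genes showed 17 rises and 1 fall among 21, also adjusted over the list alone, with a median of 0.86 (camera, adjusted p = 1.62e-34, adjusted p = 0.00334 with an estimated correlation). Of 42 glutathione S-transferases 22 rose and 1 fell (23 and 4 adjusted over the list alone, camera, adjusted p = 9.29e-22, adjusted p = 0.00821 with an estimated correlation), with gst-5 at log2 2.55 ± 0.104 and gst-38 at 3.32 ± 0.095. These were the 4 of 14 camera calls that held with an estimated correlation. Cytochrome P450 genes had 17 rises and 6 falls among 66 (18 and 7 adjusted over the list alone, camera, adjusted p = 0.000424, adjusted p = 0.285 with an estimated correlation), and heat shock genes 8 rises and no fall among 15 (10 and 1 adjusted over the list alone, camera, adjusted p = 0.001, adjusted p = 0.221 with an estimated correlation). The 17 cascade genes had 8 rises and 1 fall (10 and 1 adjusted over the list alone, camera, adjusted p = 0.0059, adjusted p = 0.286 with an estimated correlation), with tir-1 at log2 0.81 ± 0.056.

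Falls were seen in cuticle, muscle and intracellular pathogen response genes. Of 149 collagens 64 fell and 7 rose (68 and 7 adjusted over the list alone, camera, adjusted p = 1.33e-07, adjusted p = 0.221 with an estimated correlation), with col-145 at log2 -0.81 ± 0.052. Of 28 muscle markers 10 fell and none rose (11 and 1 adjusted over the list alone, camera, adjusted p = 0.0098, adjusted p = 0.44 with an estimated correlation), with the troponin gene tni-1 at -0.62 ± 0.054, a list call lost without rotr-1 replicate 2 on PA14. Of 45 intracellular pathogen response genes 9 fell and 5 rose (10 and 5 adjusted over the list alone, camera, adjusted p = 0.0274, adjusted p = 0.285 with an estimated correlation), with eol-1 at -1.16 ± 0.081, a call lost in DESeq2 and without rotr-1 replicate 2 on PA14. Lysozymes had 5 falls and 3 rises among 12, also adjusted over the list alone (camera, adjusted p = 0.0145, adjusted p = 0.372 with an estimated correlation). Sperm genes had 21 falls among 57 (26 adjusted over the list alone, camera, adjusted p = 0.000562, adjusted p = 0.591 with an estimated correlation). Lipid genes had 17 falls and 9 rises among 41 (18 and 11 adjusted over the list alone, camera, adjusted p = 0.0145, adjusted p = 0.221 with an estimated correlation), and 3 of 6 vitellogenins fell (4 adjusted over the list alone, camera, adjusted p = 0.0274, adjusted p = 0.591 with an estimated correlation), the latter call lost without rotr-1 replicate 2 on OP50 or replicate 1 on PA14. Over all genes 1549 rose and 1491 fell (edgeR), of which 239 and 146 changed at least 2-fold. At an adjusted p under 0.01 the count was 1935, and in limma on log2(TPM + 1) 62.2% of called genes were higher, against 51% in edgeR.

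**Figure D3:**
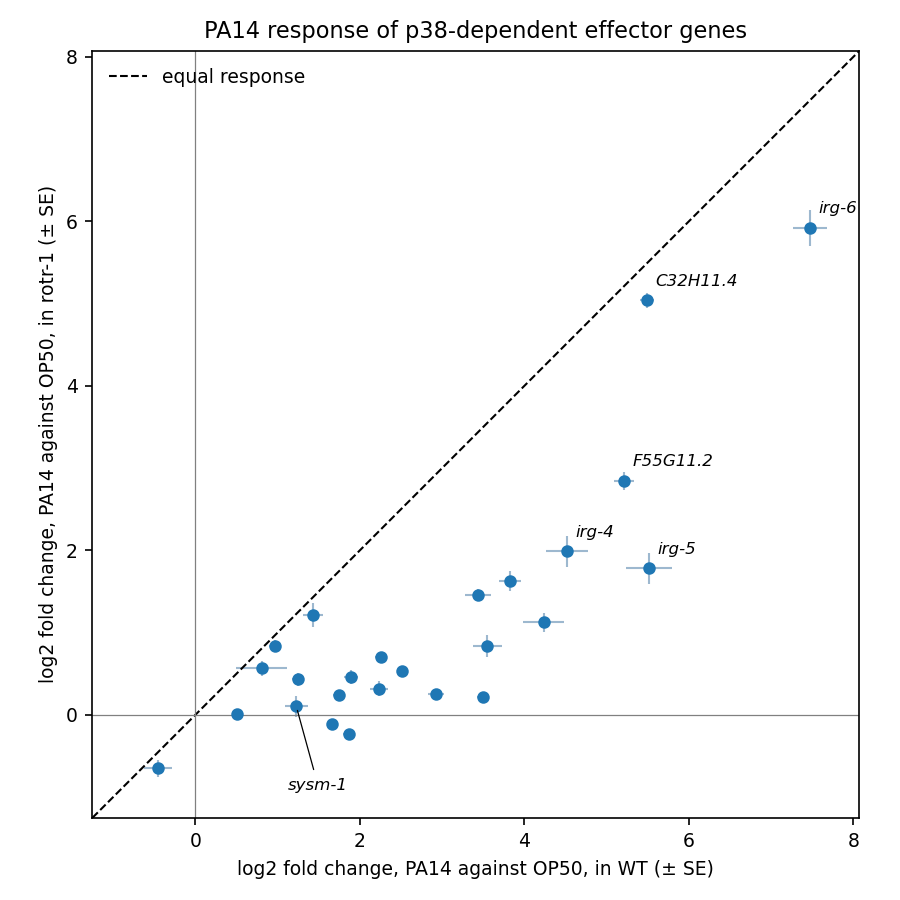
Log2 fold change of PA14 against OP50 in wild type (horizontal axis) and in rotr-1 (vertical axis) for the 25 tested p38-dependent effector genes, with bars of ± 1 SE and a dashed line of equal response. Medians were 2.25 in wild type and 0.57 in rotr-1, and all 25 points lie below the line.

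The difference between the PA14 responses of the genotypes was tested as an interaction. By log2 fold change, most p38-dependent effectors rose less in rotr-1 or did not rise there. Of 25 tested members 20 had a negative difference and none a positive one (21 and 0 adjusted over the list alone), with a median difference of log2 -1.78 (camera, adjusted p = 6.47e-108, adjusted p = 0.00146 with an estimated correlation). The difference was log2 -3.74 ± 0.348 SE for irg-5 (n = 3 per group, edgeR, adjusted p = 0.000151), -2.53 ± 0.329 for irg-4 and -1.13 ± 0.187 for sysm-1. Both irg-5 and irg-4 started from a higher level on OP50 in rotr-1, and they reached higher CPM on PA14 there than in wild type. Their negative differences are thus of folds, not of levels reached. The irg-6 difference of -1.55 ± 0.562 did not pass (edgeR, adjusted p = 0.0759), although it passed in DESeq2. It rests on 4 to 8 counts per library on OP50.

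The ZIP-2 arm followed, with a negative difference for 9 of 12 genes and a positive one for none (9 and 2 adjusted over the list alone, median -0.66, camera, adjusted p = 8.9e-10, adjusted p = 0.00388 with an estimated correlation), including irg-1 at log2 -2.41 ± 0.2 and irg-2 at -1.55 ± 0.197. These 2 lists of 12 with a camera call held with an estimated correlation. The neighbouring genes dod-21 and cld-1 rose to 154 and 137 CPM on PA14 in wild type and reached 12 and 8.69 CPM in rotr-1, differences of log2 -6.11 ± 0.446 and -5.51 ± 0.385. Of 45 intracellular pathogen response genes 12 had a negative and 1 a positive difference (13 and 1 adjusted over the list alone, camera, adjusted p = 8.24e-05, adjusted p = 0.099 with an estimated correlation). For vhp-1 the difference was -0.72 ± 0.106. For tir-1 it was -0.27 ± 0.084 (edgeR, adjusted p = 0.0318), a call lost in most fits without 1 library.

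Some genes responded more positively to PA14 in rotr-1. Of 84 ribosomal protein genes 40 had a positive difference (65 adjusted over the list alone, median 0.21, camera, adjusted p = 1.18e-12, adjusted p = 0.458 with an estimated correlation), beside the fall that they showed on PA14 in wild type. Of 6 vitellogenins 3 had a positive difference (4 adjusted over the list alone, camera, adjusted p = 8.24e-05, adjusted p = 0.446 with an estimated correlation). This was a smaller fall, with list medians of -1.63 in wild type and -0.605 in rotr-1. On OP50 the list already stood lower in rotr-1, by a median of -3.16. The stearoyl-CoA desaturase gene fat-7 went from 16 to 3.90 CPM in wild type and from 11.9 to 13 CPM in rotr-1 (difference 2.15 ± 0.213). Over all genes 1006 had a positive and 1180 a negative difference (edgeR), or 2186 in total, of which 97 and 263 were at least 2-fold. At an adjusted p under 0.01 the count was 1083, and in limma on log2(TPM + 1) 16.7% of called differences were positive, against 46% in edgeR.

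The response to PA14 was largely shared in direction between the genotypes, and rises, by log2 fold change, were more often smaller than larger in rotr-1. Of 576 genes that rose at least 2-fold in wild type, 369 also rose in rotr-1, 8 fell and 199 were not called. The interaction was called towards a smaller or opposite change for 350 of them and a larger one for 9, and the median change was log2 1.65 in wild type and 0.60 in rotr-1. Of 275 genes that fell at least 2-fold in wild type, 172 also fell in rotr-1, and 133 changed less and 5 more by the interaction (median -1.51 and -0.71). Selection in 1 genotype favours a smaller change in the other, so genes were also selected in rotr-1 and on the mean of both, a step added after the values were seen. Of 239 genes that rose at least 2-fold in rotr-1, 60 rose less and 31 more there than in wild type (median 1.70 in wild type and 1.45 in rotr-1), and of 383 with a mean rise of at least 2-fold, 187 rose less and 18 more (2.02 and 1.11). Of 146 genes that fell at least 2-fold in rotr-1, 26 fell less and 26 more (-1.40 and -1.44), and of 174 with such a mean fall, 70 fell less and 12 more (-1.75 and -1.26), so a smaller fall depended on the selection. Across 16924 genes, which are not independent replicates, the responses correlated with Pearson r = 0.554 and Spearman rho = 0.448. They shared 1147 rises and 845 falls, against 250.3 and 304.2 for independent lists, and 85 genes were called in opposite directions. The rotr-1 effects on the 2 bacteria, which share no library, correlated with r = 0.854 and rho = 0.862, with 4924 shared rises and 4776 shared falls, against 2172 and 1835.5 for independent lists.

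The rotr-1 effect on OP50 and the PA14 response of wild type overlapped, although both were measured against the same 3 libraries. They shared 2040 rises and 2773 falls, against 1035.1 and 1195.8 for independent lists, and 497 genes were called in opposite directions. Their covariance across genes was 0.274, against 0.0204 in 20 simulations of unchanged groups against the same controls. The correlation was 0.467 (rho 0.552), below the simulated mean of 0.562, since shared controls alone correlate changes that are all noise. The 3 control libraries cannot be split into parts of at least 2, so part of the shared calls may come from them.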

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

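The counts of other groupings were planned before the results were seen, and every other test of an explanation given here was chosen afterwards.

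The PA14 response differed between the genotypes, by the interaction test, for 12 gene lists and for 57 of 64 genes that the fixed rule names. Of these, 22 came from its fixed set and its largest changes, and the others were members of these lists. The rule takes largest changes and list members only where they passed, so that count is no support. Among the genes taken in every comparison, irg-5, irg-4, irg-1, irg-2, sysm-1, vhp-1 and tir-1 passed and the others did not. List medians of the difference (log2, rotr-1 minus wild type) were -1.78 for p38 effectors, -0.66 for the ZIP-2 arm, -0.53 for the intracellular pathogen response, -0.13 for C-type lectins, -0.085 for autophagy, -0.16 for the endoplasmic reticulum unfolded protein response, -0.16 for collagens and -0.092 for sperm genes. Positive medians were 0.87 for vitellogenins, 0.21 for ribosomal proteins, 0.13 for the vacuolar ATPase and 0.11 for germline genes. With an estimated correlation the p38 and ZIP-2 calls held (camera, adjusted p = 0.00146 and 0.00388), and the other 10 did not (camera, adjusted p = 0.099 to 0.761). The vacuolar ATPase and germline medians turned negative under limma on TPM, and the calls for lectins, autophagy, collagens, sperm, vacuolar ATPase and germline genes were each lost in several settings.

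Single genes with a smaller or opposite log2 fold change on PA14 in rotr-1 were dod-21 (-6.11), cld-1 (-5.51), clec-174 (-4.43, from 2 to 7 counts per wild-type library on OP50), C17H12.6 (-4.12), ugt-18 (-4.04, from 1 to 3 counts per wild-type library on OP50), irg-5 (-3.74), clec-67 (-3.28), F33H12.7 (-3.18), irg-4 (-2.53), irg-1 (-2.41), irg-2 (-1.55), sysm-1 (-1.13), vhp-1 (-0.72) and tir-1 (-0.27). Positive differences, which can be a smaller fall, were found for fat-7 (2.15), rips-1 (2.12), Y48E1B.8 (2.04), clec-166 (1.98), vit-1 (1.79), sdz-24 (1.72), hrg-7 (1.59) and F42A10.7 (1.54).

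Each comparison of 3 libraries with 3 allows only 10 splits, too few for a share under 0.05. The real split was the 1 with the most called genes in each, at 6188 for PA14 in wild type, 12266 for rotr-1 on OP50, 11039 for rotr-1 on PA14 and 3040 for PA14 in rotr-1, and the highest other split gave 0 in each (edgeR). For the interaction 6 of 100 regroupings of genotype within each bacterium gave as many genes as the real 2186, the real 1 included, so chance is not excluded by that count, and the highest other gave 9145. The count is a poor measure of chance here, because all 5 others kept the genotypes whole on 1 bacterium and mixed them on the other, which turns the genotype difference into an interaction. These point to a structure of the samples, since the 24 regroupings of that kind gave 19 to 9145 and the 75 that mixed the genotypes on both bacteria gave 0.

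Most tested genes differed between rotr-1 and wild type on OP50, together with markers of molting, cuticle, yolk and germline. Higher depth of the mutant libraries and a length trend between libraries are argued against, since 11850 genes were called after thinning to equal depth and 12317 with length offsets, beside 12266. A different point in the molting cycle or in development stays open and may account for part of the pattern. Slopes on the molting index among libraries of 1 group on PA14 correlated across 16892 genes outside the list with the rotr-1 effect on OP50 at 0.253, the highest of 36 orders of the index, although the next gave 0.251 and the value came from rotr-1 (0.277) rather than wild type (0.055). With the index as a covariate the calls fell to 253, with the median change of the genes called before going from 0.597 to 0.336 and the median standard error from 0.0992 to 0.452, since the index differs mainly between the genotypes, and a direct effect of the genotype also stays open.

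The smaller PA14 response of the p38 effectors in rotr-1 was weighed against a shared upper limit of expression, depth and stage. A level on PA14 that neither genotype can exceed would leave members equal there, but 15 of 25 were lower in rotr-1 than in wild type on PA14 and 9 were higher. Single members thus mostly did not end at a shared level, although the list means were close (5.84 log2 CPM in wild type and 5.9 in rotr-1). Of 16924 tested genes 11039 differed between the genotypes on PA14, so the count does not separate a limit from that general difference. Depth is argued against, as the median difference was -1.95 after thinning, beside -1.78. It was -1.73 with the molting index as a covariate, but the index differed between the genotypes by 1.47 log2 CPM on OP50 and 1.3 on PA14, so that the covariate nearly cancels in this difference and a response that depends on stage cannot be told apart from the genotype. A weaker induction in rotr-1 stays open beside it, as does a smaller response from a raised baseline, which was not separated because the level on OP50 enters the difference itself.

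The higher intracellular pathogen response genes in rotr-1 on OP50 were weighed against stage, shared reads and infection. With the molting index the list median was 1.5, beside 2.04 without it, and the list was still called (camera, adjusted p = 3.87e-18). This cannot decide on stage, because the index differs mainly between the genotypes. With it the median standard error over all genes rose from 0.0992 to 0.452. Reads shared among pals paralogs are argued against as the whole cause, as 8 of 9 members outside that family were higher too. These included eol-1 and cul-6, beside skr and F26F2 genes that may share reads among themselves. The split of reads among the pals genes was not tested, so their single values stay uncertain. An unseen infection of all mutant cultures could raise the same genes and cannot be told apart from the genotype, because the lowest mutant library, at a list mean of 1.93 log2 CPM, lay above the highest wild-type library at 0.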

How the results depend on the processing

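Thinning, transcript length offsets and the molting covariate were chosen after the results were seen, and the other settings were planned. The cause of a moved value was not tested unless it is given. Called genes at 2-fold or more numbered 851, 2946, 2026, 385 and 360 for PA14 in wild type, rotr-1 on OP50, rotr-1 on PA14, PA14 in rotr-1 and the interaction (in this order below), and an adjusted p under 0.01 left 1935 and 1083 in the last 2, by construction. For PA14 in rotr-1 limma on log2(TPM + 0.1) called 1972. The molting covariate left 253 and 178 calls for rotr-1 on OP50 and PA14, 248 and 169 of them shared with 12266 and 11039. Median standard errors widened to 0.452 and 0.403. The median change of the genes called before also fell, from 0.597 to 0.336 and from 0.487 to 0.278, and 67.9 and 63% of them kept their sign. Named genes changed sign in 20 and 24 cases, none past the threshold. The p38 list kept its direction in every setting and comparison. On PA14 it (rotr-1 against wild type) had a median of -0.75 and a call with the molting covariate (camera, adjusted p = 1.29e-05), and on OP50 it kept 1.23 but not its call with an estimated correlation (camera, adjusted p = 0.118). With an estimated correlation 2, 2, 1, 4 and 2 lists were called, against 14, 16, 14, 14 and 12. For PA14 in wild type limma on log2(TPM + 1) called 8 lists, and 9 with a minimum mean TPM of 1. Limma on log2(TPM + 0.1) moved the median change of all genes to 0.279 from 0.0821 for rotr-1 on OP50, to 0.127 from -0.0281 for PA14 in wild type and to -0.10 from 0.0164 for the interaction, and calls were judged against 0, not these medians. Without a filter 25.2% of interaction calls were positive, against 46%. The correlation of rotr-1 effects between bacteria (0.854) was 0.738 in DESeq2, 0.572 without a filter, 0.895 with the stricter filter, 0.764 in limma at a pseudocount of 0.1 and 0.914 with the molting covariate. That of PA14 responses (0.554) was 0.197 without a filter, 0.741 with the stricter filter, and 0.606, 0.653 and 0.399 in limma at a pseudocount of 1, at 1 with the minimum mean, and at 0.1. The overlap with shared controls (0.467) was 0.364 with the molting covariate. The atf-7 change in rotr-1 on OP50 (-0.15) reversed to 0.086 in all 3 limma tests on TPM.

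Leaving out 1 library at a time gave 4927 to 5423, 11559 to 12081, 10121 to 10663, 2268 to 3043 and 1510 to 2720 genes, and p38 list medians of 2.22 to 2.37, 1.14 to 1.37, -0.38 to -0.31, 0.52 to 0.65 and -1.89 to -1.74. List calls were 13 to 16, 15 to 17, 14 to 15, 12 to 17 and 8 to 15, and the 3 correlations 0.824 to 0.837 (rotr-1), 0.476 to 0.536 (PA14) and 0.441 to 0.516 (shared controls). Replicate numbers did not pair the libraries, as correlations of same-numbered libraries ran from -0.056 to 0.24, with 1 of 18 over 0.1, and 2 of 12 libraries fitted best with their own number in every group. With the replicate block 6368, 12275, 11025, 3103 and 2362 genes were called. Fits of the libraries of the compared groups alone called 6967, 12062, 10898 and 2382 genes, leaving out the interaction. Of 359 named gene values 354 kept direction and call with DESeq2 size factors, 354 in DESeq2, 353 without a filter, 356 after thinning, 353 with length offsets and 339 in limma on log2(TPM + 1). At the real depth, spread and 3 libraries per group, recovery at 1.5-fold was 46.3% for the simulated interaction, and depth alone was not varied there.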

Other observations

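The groupings given here were chosen after the values were seen, and no further test was run on them.

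Genes that lie close together on chromosome IV of WBcel235 did not respond alike. On PA14 in wild type C32H11.4 (12921264 to 12923296) and irg-6 (12912722 to 12914969) rose by log2 5.49 ± 0.091 and 7.48 ± 0.205 SE, and in rotr-1 they rose by 5.04 ± 0.093 and 5.92 ± 0.218. Next to them cld-1 (12935011 to 12936271) reached 137 CPM on PA14 in wild type and 8.69 CPM in rotr-1, and dod-21 (12936738 to 12937988) reached 154 and 12 CPM. F55G11.2, further along (12967445 to 12969289), reached 326 CPM in wild type and 86.5 CPM in rotr-1. On OP50 the levels of cld-1 and dod-21 were higher in rotr-1 (6.03 and 9.47 CPM) than in wild type (2.04 and 1.76 CPM).

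A stretch of chromosome II held math-38, fbxa-163 and C08E3.13. Among genes with a mean of at least 5 CPM and no overlap between libraries, math-38 and fbxa-163 were in the 8 largest rises in rotr-1 on both bacteria. C08E3.13 was among them on PA14 only. The MATH domain gene math-38 (1577378 to 1579986) was at 0.592 and 0.516 CPM in wild type on OP50 and PA14 and at 30.04 and 24.8 CPM in rotr-1. The F-box gene fbxa-163 (1609252 to 1610730) went from 0.186 and 0.713 CPM to 22 and 41.5 CPM. C08E3.13 (1631995 to 1632316) went from 1.25 and 0.378 CPM to 16 and 10.9 CPM. A sequence difference between the strains in this stretch was not examined here, and the stretch is not linked to rotr-1 on chromosome III. Aspartyl protease genes went in opposite directions on PA14, as asp-14 rose from 50.5 to 425 CPM in wild type and from 11 to 96.1 CPM in rotr-1, while asp-13 fell from 238 to 20.5 CPM and from 49.3 to 4.78 CPM. The folate transporter gene folt-2 fell from 474 to 61.1 CPM in wild type and from 169 to 35.2 CPM in rotr-1.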
